A study of Caenorhabditis elegans with 18 samples.

How the data were processed

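Total RNA of whole C. elegans at the L4 stage was measured in 18 libraries, 9 of wild type (A to I) and 3 each (A to C) of a dpf-3 null, mut-2(ne3370) and mut-7(ne4255). Per the labels' protocols, worms were grown at 15 °C on peptone-rich plates with NA22 bacteria, and total RNA went into stranded total RNA libraries read as pairs of 75 bases. Per the submitters' processing notes, cutadapt 2.3, STAR 2.7.0f and featureCounts 2.0.0 were used with the genome ce11; the role and settings of each tool, the strand setting and the treatment of reads with several matches are not stated. The table deposited by the authors holds raw counts, whole numbers whose sum differs by library. Of its 75393 features 20134 carry a gene identifier and 55259 are intervals named by coordinates alone, and all columns of values were matched to a library. Gene symbols, biotypes and places came from an Ensembl annotation of WBcel235, which holds 20055 of the identifiers; 79 were not found. Of the gene counts of 1000 or more, 63.8% were even.

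Total counts per library ran from 24931772 to 32792936. Intervals took 0.527 to 0.674% of the counts, mitochondrially encoded genes 1.07 to 2.05% and the 10 most abundant genes 5.19 to 6.15%. Between replicates of a group the mean chi-square per gene, which is near 1 for counting error alone, was 6.04 to 501. Where a gene had no counts in a group, the smallest fold was taken from a floor of 3 counts. For 62 tested genes the counts equalled those of another gene, and they are named as copies where they appear.

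Gene counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr on group (16310 genes), scaled by TMM, and fitted with a quasi-likelihood model of the 4 group means with robust estimation. Each mutant was compared with wild type and with each other mutant by glmQLFTest, p-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05, any fold change. CPM were taken with TMM-scaled library sizes. The method was tested on data simulated for the dpf-3 null and wild type with 200 changed genes. With all 9 wild-type libraries 29.9, 56.7 and 78.8% of 1.5-fold, 2-fold and 4-fold changes were recovered (0.901% false calls). With wild type A to F alone 79.1, 97 and 100% were recovered (9.36% false calls, above the nominal 5%). Rates may differ for real mutants.

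Gene lists were fixed before the data were examined; 30 of 32 had at least 3 tested members, and transposon genes and ribosomal RNA matched 0 genes. They cover germline and sperm genes, small RNA pathways and targets, chromatin, yolk, cuticle and moulting, tissue markers, stress and immune responses, receptor and F-box families, and ribosomal and respiratory proteins. Sets were tested with camera of limma 3.58.1, two-sided, with a preset correlation between genes of 0.01, adjusted over all lists and the 3 mutants. camera with an estimated correlation and fry were alternatives. Members were also counted with p-values adjusted over the list alone. Where 0 members were called, counts at an unadjusted p under 0.05 and by DESeq2 were made.

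The rule for named genes was fixed before the data were examined. It takes dpf-3, mut-2 and mut-7 in every group, and for each mutant the 8 highest and 8 lowest fold changes among called genes with a mean of at least 1 CPM and all 3 mutant libraries outside the range of the 9 wild-type libraries. It adds up to 4 called members of smallest adjusted p per list discussed (or 2 of highest level where fewer are called), 8 genes called the same way in all 3 mutants with the largest smallest change, and wago-1, wago-3, prg-1, csr-1, hrde-1, alg-3 and alg-4. For pairs of mutants it takes the 4 highest and 4 lowest. The choice of the 9 lists whose members are named, and the limit of fold changes to genes called in the comparison, were made after values were seen. The Argonaute wago-3 is ppw-2 in the table.

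Overlaps between mutants were set beside the number shared by independent calls, beside 10 simulated unchanged sets with the same controls, and beside fits in which the wild-type libraries were divided between the mutants. X-linked against autosomal genes and pseudogenes against protein-coding genes were compared with two-sided Fisher tests. The samples were also split in every or up to 100 other ways (of 220 possible for 9 and 3 libraries, 84 for 6 and 3, and 10 for 3 and 3). The comparison with all 9 wild-type libraries was first run at 40 splits and then at 100, and both results were seen; 2 were as large as the real one each time.

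Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE and upper-quartile scaling, no filter, a filter of over 1 CPM in at least 3 libraries, removal of ribosomal and mitochondrial RNA, fits of the 2 groups only, no robust estimation, wild type A to F, G to I, A to C or D to F only, the replicate letter as a block with wild type A to C, each library left out, a minimum of 2-fold, an adjusted p under 0.01, and the set tests above. Chosen after seeing the data were calls made against both wild type A to F and G to I, each in its own fit, and a fit of the intervals with the library sizes and TMM factors of the genes. The intervals were left out of the main fit because they carry no gene name. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and in R with the data.table package (1.17.8); plots were drawn with matplotlib 3.10.9.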

Results

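Total RNA of whole L4 C. elegans grown at 15 °C was sequenced in 18 libraries. There were 9 of wild type (A to I) and 3 each (A to C) of a dpf-3 null, mut-2(ne3370) and mut-7(ne4255). Counts per library ran from 24931772 to 32792936. Expression is given as CPM, the count of a gene scaled to the library size, mean ± SD over libraries, and a fold change as the log2 of mutant over wild type with its standard error (SE). Adjusted p-values come from edgeR, and a gene was called at an adjusted p under 0.05 with any fold change. No label names separate cultures, so replicate spread may be technical. For the main p-values it includes the gap between wild type A to F and G to I. Limits drawn from a count of 0 cover counting error only. Coordinates are those of ce11 (WBcel235).

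The 3 genes that the genotypes name were read first. dpf-3 (WBGene00001056, I:6838354-6843343), which encodes a dipeptidyl peptidase, stood at 183 ± 8.5 CPM in wild type A to F (n = 6) and 260 ± 11.9 CPM in wild type G to I (n = 3). In the dpf-3 null it was 8.08 ± 0.578 CPM (n = 3), a log2 fold change of -4.69 (SE 0.18, adjusted p = 1.01e-10), while mut-2 and mut-7 worms had 187 ± 6.09 and 199 ± 6.06 CPM. mut-2 (WBGene00003499, I:6356614-6358410), also called rde-3, encodes a nucleotidyltransferase that adds UG repeats to RNA. It was at 10.2 ± 0.922 CPM in mut-2 worms, against 16.7 ± 1.68 CPM in wild type A to F and 42.3 ± 2.67 CPM in G to I (log2 fold change -1.31, SE 0.37, adjusted p = 0.0194). Without mut-2 library B or C and in a fit of the 2 groups that call was lost, at log2 fold changes of -1.27, -1.33 and -1.38. Its level was 15.5 ± 1.06 CPM in the dpf-3 null and 18.6 ± 1.17 CPM in mut-7 worms. mut-7 (WBGene00003504, III:9539031-9542380) encodes a protein with a 3'-5' exonuclease domain that sits in mutator foci. Its mRNA was at 83.7 ± 2.14 CPM in mut-7 worms, between wild type A to F (71.9 ± 2.66 CPM) and G to I (113.5 ± 4.69 CPM), and not called against all 9 (edgeR, adjusted p = 0.92), so its level does not check that label. It was at 71.6 ± 3.29 CPM in the dpf-3 null and 62.9 ± 2.68 CPM in mut-2 worms.

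**Figure D1:**
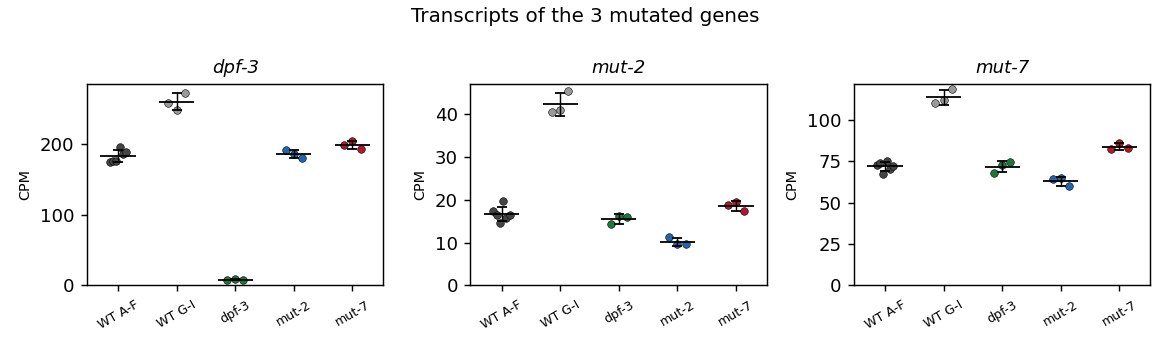
Level of dpf-3, mut-2 and mut-7 in CPM on the y axis for each group of libraries, with bars at the mean, error bars of 1 SD and a point per library. dpf-3 fell from 183 CPM in wild type A to F to 8.08 CPM in the dpf-3 null, whereas mut-7 was at 83.7 CPM in mut-7 worms and 71.9 CPM in wild type A to F.

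The wild-type libraries fell into 2 sets, A to F and G to I, which differed in genes of the late germline and of yolk. All 30 tested genes of the major sperm proteins, which drive sperm crawling, were higher in G to I than in A to F, with a median log2 fold change of 10.40. All 30 oocyte and maternal genes were higher as well (median 3.43), and so were all 6 vitellogenins, the yolk proteins made in the adult intestine (median 14.24). vit-6 (WBGene00006930) had 0.251 CPM in A to F and 7829 CPM in G to I, and msp-31 (WBGene00003429) had 1.39 and 368 CPM. Across 16310 genes, 6307 were higher and 6599 lower in G to I than in A to F. On the axis that joins the mean of A to F (0) to that of G to I (1), the dpf-3 null lay at 0.109 ± 0.0031, mut-2 at 0.276 ± 0.014 and mut-7 at 0.548 ± 0.027 (SD, n = 3 each). The labels do not say which wild-type libraries are the controls of which mutant; in the order of the samples G to I stand between the dpf-3 null and mut-2. The mutants were compared with all 9, and what each count and fold change measures depends on that choice.

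**Figure D2:**
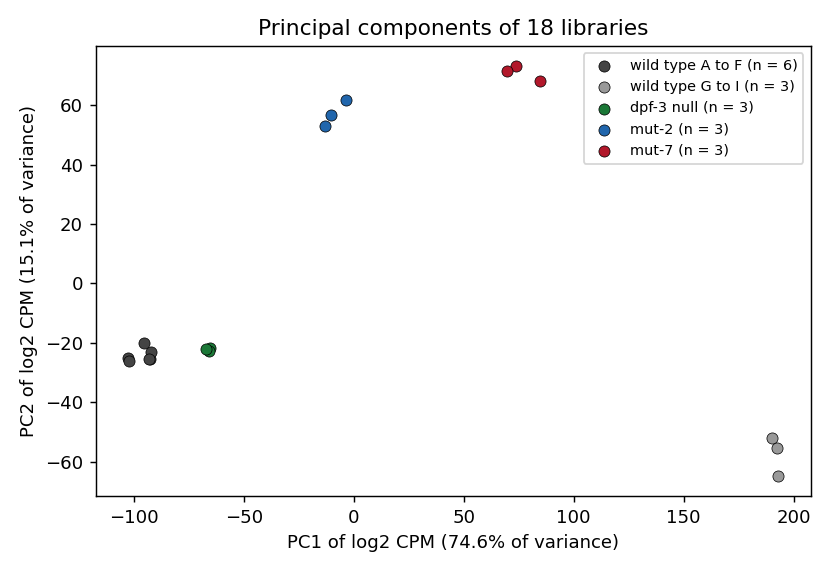
Principal components of log2 CPM over the 18 libraries, with 1 point per library and a colour per group; the x axis is PC1 (74.6% of the variance) and the y axis PC2 (15.1%). Wild type G to I lie apart from wild type A to F along PC1, and mut-7 worms lie between them.

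The comparison of the dpf-3 null with wild type asked which transcripts change without a protease that, by the title of the series, bears on the processing of Argonaute proteins. Among the genes that rose most were F07B7.1, F07B7.2 and C38D9.2. F07B7.1 (WBGene00021106, V:8830183-8830474) had 9.83 ± 0.95 CPM in the dpf-3 null (n = 3), 0.522 CPM in wild type A to F and 0.39 CPM in G to I, a log2 fold change of 4.35 (SE 0.16, adjusted p = 8.52e-11). Its counts equal those of a second copy (WBGene00017185, V:8872277-8872568), so the copies cannot be told apart. F07B7.2 (WBGene00021107, V:8828740-8828884), next to it and also present as a second copy (WBGene00017186), rose by 4.22 (SE 0.14, adjusted p = 3.85e-11) to 6.04 ± 0.47 CPM. C38D9.2 (WBGene00008010, V:17567513-17571603), a known target of endogenous small RNAs, rose from 3.59 ± 0.36 CPM in A to F and 2.28 ± 0.138 CPM in G to I to 35 ± 2.11 CPM (log2 fold change 3.47, SE 0.16, adjusted p = 8.72e-10). ZC15.3 (WBGene00013832, V:20303588-20304908) rose from 0.58 CPM in A to F and 0.554 CPM in G to I to 9.17 ± 0.417 CPM (adjusted p = 3.4e-06), and F55B11.6 (WBGene00044249) rose by 3.01 on the log2 scale (adjusted p = 9.24e-06). The collagen genes col-114 (WBGene00000688, 3.86) and col-164 (WBGene00000737, 3.33) were also called, at 0.383 and 0.373 CPM, and lost the call in 23 and 8 of the other settings tried. Y73C8B.5 (WBGene00044525) had no counts in wild type and 0.0698 CPM in the dpf-3 null, and also lost its call in 23 settings.

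After dpf-3 itself, the genes that fell most in the dpf-3 null were ZK218.5, R04B3.2 and a set at the left end of the X chromosome. ZK218.5 (WBGene00013939, V:17101132-17102017) was at 0.0785 CPM, against 1.85 ± 1.59 CPM in wild type A to F (log2 fold change -4.31, SE 0.85, adjusted p = 0.0267). R04B3.2 (WBGene00019867, X:2471540-2473718) was at 0.342 CPM, against 6.13 and 3.39 CPM in the wild-type sets (-3.91, SE 0.32, adjusted p = 4.27e-06). On the left end of X, chkr-1 (WBGene00011612, X:182691-191193) fell by 2.76 on the log2 scale (adjusted p = 0.00141) and Y73B3A.20 (WBGene00022221, X:47766-48548) by 2.16 (adjusted p = 2.16e-05). Y73B3A.1 (WBGene00022203, X:42728-46924), T08D2.8 (WBGene00011613, X:194038-197901) and Y73B3A.4 (WBGene00022206, X:95959-104777) fell by 1.80, 1.78 and 1.71. The calls of ZK218.5, Y73B3A.1 and Y73B3A.4 were lost without any 1 of the 3 dpf-3 null libraries, and the first 2 in a fit of the 2 groups.

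Of 11 tested genes reported as targets of endogenous small interfering RNAs, 2 rose in the dpf-3 null and 0 fell, F07B7.2 and C38D9.2, or 4 and 0 when adjusted over the list alone. The list rose as a set (camera, adjusted p = 3.9e-08), also with an estimated correlation (adjusted p = 0.00067), but not against G to I alone (adjusted p = 0.07). Its median log2 fold change was 0.14 against all wild-type libraries, 0.41 against A to F and 0.48 against G to I, and 4 of the genes were higher than each of the wild-type sets. Of the cuticle collagens, which form the exoskeleton and are made in waves around each moult, 8 rose, 0 fell and 156 were not called. Adjusted over the list alone 23 rose and 0 fell, and by DESeq2 25 and 25. col-154 (WBGene00000727, V:11385360-11386529) rose from 368 CPM in A to F and 335 CPM in G to I to 712 ± 13.1 CPM (log2 fold change 1.00, SE 0.15, adjusted p = 0.00342), col-130 by 0.65, col-155 by 0.90 and col-98 by 1.04. The col-155 and col-98 calls were lost without any 1 mutant library, and that of col-130 without A or B. The collagens were called higher as a set (adjusted p = 1.2e-06), but not with an estimated correlation (0.099) or against G to I (0.58). Their median (0.10) and the test pointed up while their mean was -1.06, and the median was 0.64 against A to F and 0.32 against G to I.

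In the genes of the late germline, no gene was called in the dpf-3 null, and the levels lay nearer to wild type A to F than to G to I. Of 30 major sperm protein genes, edgeR called 0, or 0 higher and 30 lower when adjusted over the list alone; 30 were lower at an unadjusted p under 0.05 and DESeq2 called 30 lower. The set test called the list lower (adjusted p = 0.00025), not with an estimated correlation (0.89) and higher against A to F (5.6e-25). msp-31 was at 2.40 CPM. The median of the list was 2.06 against A to F and -8.09 against G to I, and 26 of its genes were called higher than A to F and 30 lower than G to I. Of 6 vitellogenins edgeR called 0, or 0 higher and 6 lower when adjusted over the list alone; 6 were lower at an unadjusted p under 0.05 and by DESeq2. vit-6 was at 1.68 CPM and vit-2 (WBGene00006926) at 0.279 CPM, and the set test called the vitellogenins lower (adjusted p = 0.03; 0.89 with an estimated correlation) but higher against A to F (0.025), with a median of 1.065 there and -12.528 against G to I. Of 30 oocyte and maternal genes 0 were called by edgeR, also when adjusted over the list alone, while 9 were lower at an unadjusted p under 0.05 and 10 by DESeq2. The set was called lower (adjusted p = 1.2e-06; 0.89 with an estimated correlation) but higher against A to F (0.0013), and its median was 0.24 against A to F and -3.11 against G to I. cbd-1 (WBGene00010351), a gene of the eggshell, was at 273 CPM in the dpf-3 null, 212 CPM in A to F and 1797 CPM in G to I.

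Among 50 genes of meiosis and germ cell proliferation edgeR called 0 in the dpf-3 null, also when adjusted over the list alone; 5 were lower at an unadjusted p under 0.05 and 1 by DESeq2. rnr-1 (WBGene00004391), a subunit of ribonucleotide reductase, was at 172 CPM, against 180 CPM in A to F and 206 CPM in G to I. The set was called lower (adjusted p = 4.5e-07; 0.89 with an estimated correlation, 0.65 against A to F), with a median of 0.04 against A to F and -0.80 against G to I. Of 76 cytosolic ribosomal protein genes 0 were called by edgeR, also when adjusted over the list alone; 2 were higher and 1 lower at an unadjusted p under 0.05, and DESeq2 called 0 higher and 1 lower. The set was called higher (adjusted p = 0.01; 0.89 with an estimated correlation, 0.81 against A to F, 0.12 against G to I), with medians of 0.05 against all wild type, 0.00 against A to F and 0.16 against G to I. Among 35 genes of the intracellular pathogen response, the transcripts that rise on infection by microsporidia or viruses, 0 rose and 1 fell, or 2 and 1 when adjusted over the list alone. The gene that fell was pals-33 (WBGene00021081), from 0.231 CPM in A to F and 0.226 CPM in G to I to 0.0464 CPM (log2 fold change -2.21, SE 0.42, adjusted p = 0.0198). skr-3 (WBGene00004809), a ubiquitin ligase subunit, was at 87.7 CPM and the helicase gene drh-1 (WBGene00001090) at 80.7 CPM, against 81.9 and 77.8 CPM in A to F. The set was not called (adjusted p = 0.76).

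Of 20 Argonaute genes, which bind small RNAs, edgeR called 0 in the dpf-3 null, also when adjusted over the list alone; 1 was higher and 0 lower at an unadjusted p under 0.05, and DESeq2 called 0 higher and 2 lower. wago-1 (WBGene00011061) was at 329 CPM, against 281 CPM in A to F and 756 CPM in G to I. ppw-2 (WBGene00004094), also named wago-3, was at 322 CPM against 306 and 379 CPM, and prg-1 (WBGene00004178), the Piwi protein, at 269 CPM against 252 and 484 CPM. csr-1 (WBGene00017641) was at 249 CPM against 243 and 546 CPM, and hrde-1 (WBGene00007624), which acts in the germ cell nucleus, at 193 CPM against 180 and 606 CPM. The spermatogenesis Argonautes alg-3 (WBGene00011910) and alg-4 (WBGene00006449) were at 3.15 and 3.83 CPM, against 1.59 and 1.48 CPM in A to F and 156 and 173 CPM in G to I. The Argonaute set was not called (adjusted p = 0.2), and its median was 0.09 against A to F and -0.77 against G to I.

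Over 16310 genes, 90 were higher and 43 lower in the dpf-3 null than in wild type, 30 and 19 of them by at least 2-fold. Of these, 84 and 38 had all 3 mutant libraries outside the range of the 9 wild-type libraries. Against wild type A to F alone the counts were 1521 higher and 1694 lower, against G to I alone 6407 and 5597. Higher than each set were 407 and lower than each 205, fewer than the 615.3 and 562.2 that independent calls would share, while 840 were higher than A to F and lower than G to I and 1228 the reverse. Without dpf-3 null A, B or C the higher genes were 31, 26 and 26 and the lower ones 11, 13 and 13; DESeq2 called 310 higher and 1229 lower and a fit of the 2 groups only 26 and 16.

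**Figure D3:**
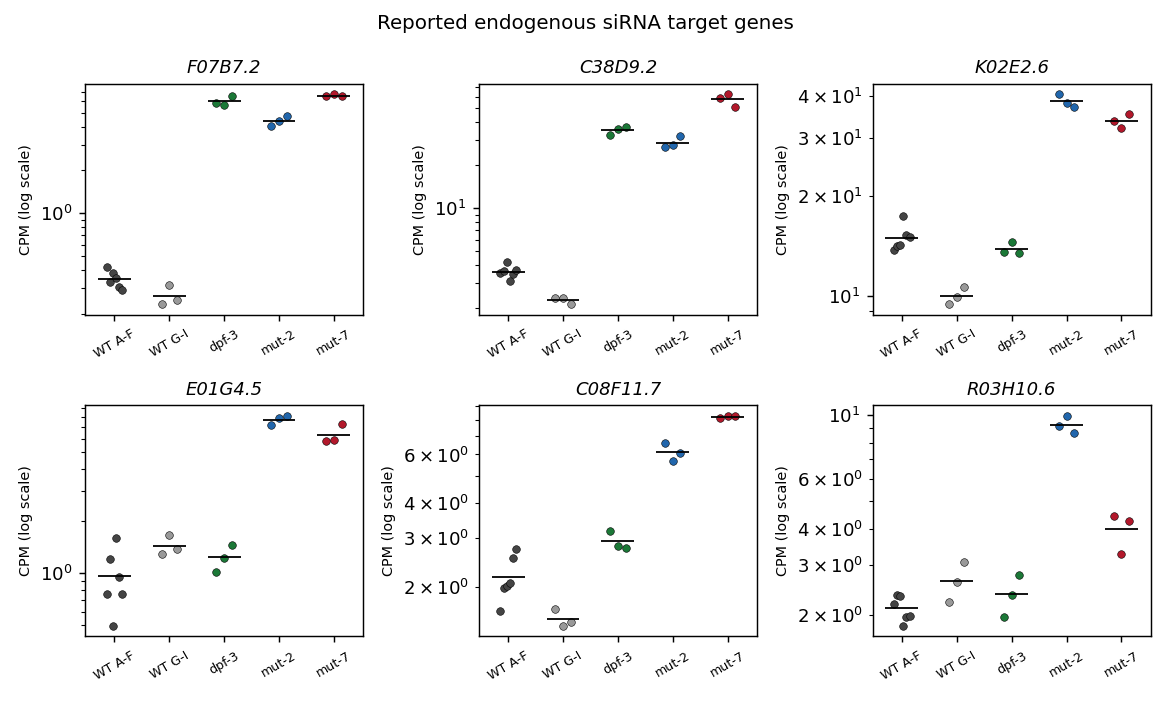
CPM on a log y axis of F07B7.2, C38D9.2, K02E2.6, E01G4.5, C08F11.7 and R03H10.6 in each library, grouped on the x axis, with a line at each mean. C38D9.2 was at 3.59 CPM in wild type A to F, 35 CPM in the dpf-3 null, 28.7 CPM in mut-2 and 57.7 CPM in mut-7 worms.

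The comparison of mut-2(ne3370) with wild type asked which transcripts change without the nucleotidyltransferase that small RNA amplification needs. Of the 11 reported targets of endogenous small interfering RNAs, 9 rose and 0 fell, or 9 and 1 when adjusted over the list alone, and the set was called (adjusted p = 4.1e-12; 8e-05 with an estimated correlation). F07B7.2 rose by 3.75 on the log2 scale (adjusted p = 3.34e-11), C38D9.2 by 3.18 (adjusted p = 1.01e-09) to 28.7 ± 2.73 CPM, and R03H10.6 (WBGene00019858) from 2.11 CPM in A to F and 2.63 CPM in G to I to 9.26 ± 0.636 CPM (2.02, SE 0.15, adjusted p = 9.81e-08). K02E2.6 (WBGene00010507) rose from 15 and 10 CPM to 38.6 ± 1.78 CPM (1.54, SE 0.14, adjusted p = 1.32e-06). The median of the list was 1.65 against all wild type, 1.90 against G to I and 1.504 against A to F, and 9 of its genes were higher than each of the wild-type sets.

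The largest rise was that of F11D11.3 (WBGene00008698, V:18757982-18760285), from 0.0411 CPM in A to F and 0.168 CPM in G to I to 26.3 ± 1.65 CPM in mut-2 worms (log2 fold change 8.23, SE 0.72, adjusted p = 7.04e-07). The next belonged largely to 1 stretch of chromosome V. C14C6.8 (WBGene00015762, V:551279-553167) rose by 7.15 on the log2 scale to 25.8 ± 4.16 CPM, ZK488.5 (WBGene00022757, V:593259-595677) by 7.11, ZK488.6 (WBGene00022758) by 6.88, nstp-7 (WBGene00019451), of a nucleotide sugar transporter family, by 6.87, C14C6.6 (WBGene00015760) by 6.72 and K06H6.1 (WBGene00019449) by 6.31. Their adjusted p-values ran up to 0.000353. Wild type G to I lay above A to F in these genes, at 1.05 against 0.0267 CPM for C14C6.6, which was at 39.1 CPM in mut-2 worms. gmd-2 (WBGene00010166, I:12292269-12293936), of a GDP-mannose dehydratase family, rose from 0.261 and 2.20 CPM to 76.3 ± 13.4 CPM (6.39, SE 0.71, adjusted p = 8.94e-06).

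Some genes were lost in mut-2 worms. tbc-18 (WBGene00018281, X:8378557-8382700), of the TBC family of GTPase-activating proteins, had no counts in the 3 libraries, at least 215-fold lower than wild type, which had 10.1 CPM in A to F and 6.72 CPM in G to I. It was at 10.2 CPM in the dpf-3 null and 9.16 CPM in mut-7 worms. F41D9.2 (WBGene00018282, X:8382706-8384945), the gene beside it, fell by 4.14 on the log2 scale to 0.405 CPM (adjusted p = 2.52e-06). Y73B3A.20 also had no counts, at least 213-fold lower, and chkr-1 and Y73B3A.4 fell by 4.06 and 3.85 (adjusted p = 4.59e-06 and 6.03e-07). cest-2.2 (WBGene00013874, V:14171645-14175355), a carboxylesterase gene, fell from 24.9 CPM in A to F and 36 CPM in G to I to 0.0933 ± 0.111 CPM (-8.20, SE 0.57, adjusted p = 6.59e-08). R13D11.4 (WBGene00020058, V:810793-814726) fell by 5.98 (adjusted p = 2.72e-10), C35A11.2 (WBGene00016429) by 5.29 (adjusted p = 2.79e-06), ttr-10 (WBGene00017600), a transthyretin-related gene, by 4.32 (adjusted p = 1.1e-09) and F36D1.8 (WBGene00009467) by 4.30 (adjusted p = 0.00299).

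Of the 35 genes of the intracellular pathogen response, 18 rose in mut-2 worms and 0 fell, or 20 and 0 when adjusted over the list alone. The set was called higher (adjusted p = 1.6e-11), also with an estimated correlation (adjusted p = 0.0026), with a median of 0.66 against A to F and 1.16 against G to I. The F-box gene fbxa-182 (WBGene00018353) rose from 2.01 CPM in A to F and 2.52 CPM in G to I to 15.9 ± 0.348 CPM (log2 fold change 2.87, SE 0.15, adjusted p = 2.75e-09), fbxa-158 (WBGene00015602) by 2.47, skr-4 (WBGene00004810) by 1.08 and skr-3 by 0.76. Of the cuticle collagens 39 rose, 17 fell and 108 were not called, or 39 and 20 when adjusted over the list alone. col-79 (WBGene00000655) rose from 18.8 and 20.3 CPM to 155 ± 20.4 CPM (3.00, SE 0.09, adjusted p = 1.97e-12), col-110 (WBGene00000684) from 6.78 CPM in A to F to 142 CPM (4.03, SE 0.23, adjusted p = 6.33e-09), col-109 by 1.26 and col-98 by 2.23. The collagens were not called as a set (adjusted p = 0.1); their median (-0.22) and mean (-0.16) were negative while the test pointed up, and the median was 0.20 against A to F and 0.51 against G to I.

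Of the 50 genes of meiosis and germ cell proliferation, 0 rose and 19 fell in mut-2 worms (1 and 27 adjusted over the list alone). The set was called lower (adjusted p = 4.3e-11, or 0.89 with an estimated correlation). fbf-1 (WBGene00001401) and fbf-2 (WBGene00001402), PUF proteins that maintain germline stem cells, fell by 1.10 (SE 0.12, adjusted p = 6.61e-06) and 0.91 (adjusted p = 8.47e-06); fbf-1 was at 41.3 CPM in A to F, 54.2 CPM in G to I and 21.2 CPM in mut-2 worms. The Polycomb-like gene mes-6 (WBGene00003224) fell by 0.53 and the meiotic kinase gene chk-2 (WBGene00000499) by 1.05. The list median was -0.33 against A to F and -1.28 against G to I. Of 30 oocyte and maternal genes 0 rose and 3 fell, or 0 and 2 when adjusted over the list alone: lin-41 (WBGene00003026) by 1.10 (SE 0.18, adjusted p = 0.000299), daz-1 (WBGene00000935) by 1.45 and cey-3 (WBGene00000474) by 1.67 (adjusted p = 0.0488). cey-3 lost its call in 13 of the other settings, among them each that left out a mutant library. That set was called lower (adjusted p = 0.0002; 0.89 with an estimated correlation, 0.25 against A to F), with a median of -0.19 against A to F and -3.83 against G to I. Of 30 major sperm protein genes 0 were called by edgeR, also when adjusted over the list alone; 0 were lower at an unadjusted p under 0.05 and 27 by DESeq2. The set was not called (adjusted p = 0.18), with msp-31 at 6.16 CPM. Its median was 3.71 against A to F and -6.37 against G to I. Of 6 vitellogenins 0 were called, also when adjusted over the list alone; 1 was lower at an unadjusted p under 0.05 and 6 by DESeq2 (set test, adjusted p = 0.49). Their median was 5.28 against A to F and -8.68 against G to I.

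Of the 20 Argonaute genes, 2 rose in mut-2 worms and 4 fell, or 2 and 6 when adjusted over the list alone, and the set was not called (adjusted p = 0.31). vsra-1 (WBGene00007297) rose from 23.9 CPM in A to F and 41.9 CPM in G to I to 80.6 ± 3.74 CPM (log2 fold change 1.43, SE 0.19, adjusted p = 6.09e-05) and sago-1 (WBGene00019666) by 0.42 (adjusted p = 0.00345; 0.052 in a fit of the 2 groups). ppw-2 fell to 249 CPM (-0.41, adjusted p = 0.00326), sago-2 (WBGene00018921) fell by 0.30 (adjusted p = 0.00309; 0.071 with upper-quartile scaling) and csr-1 to 173 CPM (-0.99, SE 0.31, adjusted p = 0.0323), a call lost without any 1 of the 3 mut-2 libraries and in a fit of the 2 groups. wago-1 was at 209 CPM, prg-1 at 253 CPM, hrde-1 at 149 CPM, alg-3 at 8.62 CPM and alg-4 at 13.2 CPM. Of 76 ribosomal protein genes 0 rose and 14 fell, or 0 and 12 when adjusted over the list alone. rpl-24.2 (WBGene00004437) fell by 0.33 (SE 0.07, adjusted p = 0.00146), rpl-3 by 0.29, rps-3 by 0.22 and rpl-10 by 0.21; the last 3 calls were lost with upper-quartile scaling and without mut-2 B. The ribosomal set was called lower (adjusted p = 1e-06; 0.89 with an estimated correlation, 0.79 against G to I), with a median of -0.24 against A to F and -0.13 against G to I.

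Over 16310 genes, 2084 were higher and 1490 lower in mut-2 worms than in wild type, 810 and 420 of them by at least 2-fold, and 1568 and 1197 had all 3 mutant libraries outside the wild-type range. Against A to F alone 4695 were higher and 4258 lower, against G to I alone 6580 and 6361. Higher than each were 2351 and lower 2269 (1949 and 1617 if independent), while 1813 and 1237 went opposite ways. Without mut-2 A or C the higher genes were 1204 and 1209, and without mut-2 B the lower ones were 818; DESeq2 called 2862 lower and a fit of the 2 groups only gave 1179 higher.

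The comparison of mut-7(ne4255) with wild type asked the same of the exonuclease-domain protein of mutator foci. Of the 11 reported small RNA targets 9 rose and 0 fell, also when adjusted over the list alone, and the set was called (adjusted p = 4.1e-12; 8e-05 with an estimated correlation). F07B7.2 rose by 4.34 on the log2 scale (adjusted p = 1.28e-11), C38D9.2 by 4.19 (adjusted p = 3.79e-11) to 57.7 ± 6.1 CPM, and E01G4.5 (WBGene00008447) from 0.962 CPM in A to F and 1.44 CPM in G to I to 6.32 ± 0.817 CPM (2.49, SE 0.26, adjusted p = 5.25e-06). C08F11.7 (WBGene00007454) rose from 2.17 and 1.54 CPM to 8.21 ± 0.076 CPM (2.07, SE 0.16, adjusted p = 2.76e-07). The median of the list was 1.33 against A to F and 1.71 against G to I, and 9 of its genes were higher than each of the wild-type sets.

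Among the largest rises in mut-7 were cuticle genes. These may peak between the wild-type sets, where mut-7 lay, which was not tested. Of the cuticle collagens 44 rose and 5 fell (47 and 6 adjusted over the list alone). The set was called higher (adjusted p = 4.5e-10), also with an estimated correlation (0.023). col-102 (WBGene00000676, IV:604444-605876) rose to 7.23 ± 1.28 CPM from no counts in A to F and 0.0111 CPM in G to I (log2 fold change 9.85, SE 1.09, adjusted p = 9.16e-06). col-114 rose by 7.68, col-2 (WBGene00000593, IV:10084454-10085438) by 7.36 to 16.9 ± 1 CPM, col-37 (WBGene00000614, V:12166706-12167753) by 7.35 to 17.5 ± 1.19 CPM and col-164 by 7.31. cut-1 (WBGene00000851, II:11269124-11271599), a cuticlin gene, rose by 7.98 to 7.49 ± 2.69 CPM, and grl-25 (WBGene00001734, III:8962295-8965638), of the ground-like family, by 8.16 to 6.48 ± 1.01 CPM. The wild-type levels of col-102, col-37, cut-1 and grl-25 lay near 0 and mostly in library G (col-37 at 0.864 CPM), so their folds and order are uncertain; against A to F they were 10.79, 10.2, 10.84 and 9.42. Among collagens of higher level, col-79 rose by 3.29 (SE 0.09, adjusted p = 9.81e-13) to 189 ± 16.6 CPM, col-48 (WBGene00000625) by 2.31 to 768 CPM from 157 CPM in A to F and 150 CPM in G to I, col-109 by 2.42 and col-110 by 4.37. The collagen median was 0.24 against all wild type, 0.51 against A to F and 0.98 against G to I. nstp-7 rose by 7.29 (SE 0.95, adjusted p = 5.06e-05). It lies in the stretch of chromosome V described for mut-2, where the mut-7 fold changes of its neighbours are given.

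Genes at the left end of X were lost in mut-7 worms. Y73B3A.20, chkr-1 and T08D2.8 had no counts in the 3 libraries, at least 183-fold, 81.4-fold and 86.4-fold lower than wild type. AC8.3 (WBGene00007075, X:228080-229761) and its copy AC8.10 (WBGene00043988, X:237496-239177), at 4.63 CPM in A to F and 2.99 CPM in G to I, also had none (at least 82.2-fold lower), as had the 2 copies of AC8.4 (WBGene00007076 and WBGene00043989; at least 29-fold lower, from 1.54 and 1.06 CPM). Y73B3A.1 and Y73B3A.4 fell by 2.79 and 3.94 on the log2 scale (adjusted p = 8.55e-05 and 5.52e-07). F08F3.1 (WBGene00017260, V:5446138-5448721) was at 2.25 CPM in A to F, 0.714 CPM in G to I and 0 CPM in mut-7 worms.

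Of the 35 genes of the intracellular pathogen response, 14 rose in mut-7 worms and 0 fell, or 15 and 0 when adjusted over the list alone. The set was called higher (adjusted p = 6.5e-07), also with an estimated correlation (adjusted p = 0.023), but not against A to F (0.24), A to C (0.13) or D to F (0.21), with a median of 0.63 against A to F and 0.75 against G to I. skr-4 rose by 1.37 (adjusted p = 8.39e-08), fbxa-182 by 1.93 (adjusted p = 3.48e-07) to 8.28 CPM, pals-33 by 1.99 and pals-27 (WBGene00007132) by 2.35. Of 76 ribosomal protein genes 0 rose and 47 fell, or 0 and 56 when adjusted over the list alone. rpl-24.2 fell from 112 CPM in A to F and 108 CPM in G to I to 78.4 CPM (-0.49, SE 0.07, adjusted p = 5.72e-05), rps-18 by 0.24, rps-14 by 0.31 and rpl-21 by 0.28; the last 3 calls were lost with upper-quartile scaling (adjusted p = 0.15, 0.082 and 0.15). The ribosomal set was called lower (adjusted p = 1.7e-09; 0.81 with an estimated correlation, 0.33 against G to I), with a median of -0.26 against A to F and -0.19 against G to I.

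Of the 50 genes of meiosis and germ cell proliferation 0 rose and 9 fell in mut-7 worms, also when adjusted over the list alone. fbf-1 fell by 0.85 (adjusted p = 8.12e-05), fbf-2 by 0.62, mes-6 by 0.48 and the replication gene mcm-4 (WBGene00003156) by 0.48. The set was called lower (adjusted p = 2.4e-05; 0.89 with an estimated correlation, 0.19 against A to F), with a median of -0.03 against A to F and -0.98 against G to I. Of 30 oocyte and maternal genes 0 rose and 1 fell, also when adjusted over the list alone. That gene was lin-41 (-1.32, SE 0.18, adjusted p = 6.96e-05), while cbd-1 was at 318 CPM and cey-2 (WBGene00000473) at 160 CPM. The oocyte set was not called (adjusted p = 0.064); its median was 0.78 against A to F and -2.84 against G to I. Of 30 major sperm protein genes 0 were called by edgeR, also when adjusted over the list alone, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 (set test, adjusted p = 0.46). Their median was -2.03 against all wild type while the test pointed up, 6.56 against A to F and -3.65 against G to I, and msp-31 was at 31.6 CPM. Of 6 vitellogenins 0 were called, also when adjusted over the list alone, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 (set test, adjusted p = 0.91). vit-6 was at 299 CPM and vit-2 at 102 CPM, and the median was 8.50 against A to F and -5.24 against G to I. Of the 20 Argonaute genes 3 rose and 1 fell, also when adjusted over the list alone. vsra-1 rose by 0.81 (adjusted p = 0.00793; 0.05 and not called without mut-7 B), sago-1 by 0.87 (adjusted p = 3.83e-06) and wago-5 (WBGene00022877) by 1.97 (adjusted p = 0.00126), and ppw-2 fell by 0.37 to 257 CPM (adjusted p = 0.00722). wago-1 was at 334 CPM, prg-1 at 343 CPM, csr-1 at 234 CPM, hrde-1 at 254 CPM, alg-3 at 44.6 CPM and alg-4 at 62.6 CPM, and the set was not called (adjusted p = 0.63).

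Over 16310 genes, 1545 were higher and 1859 lower in mut-7 worms than in wild type, 756 and 376 of them by at least 2-fold, and 1073 and 1466 had all 3 mutant libraries outside the wild-type range. Against A to F alone 4903 were higher and 4529 lower, against G to I alone 5955 and 6402. Higher than each were 2037 and lower 2016 (1842 and 1734 if independent), while 2156 and 1427 went opposite ways. Without mut-7 A or B the higher genes were 974 and 995.

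**Figure D4:**
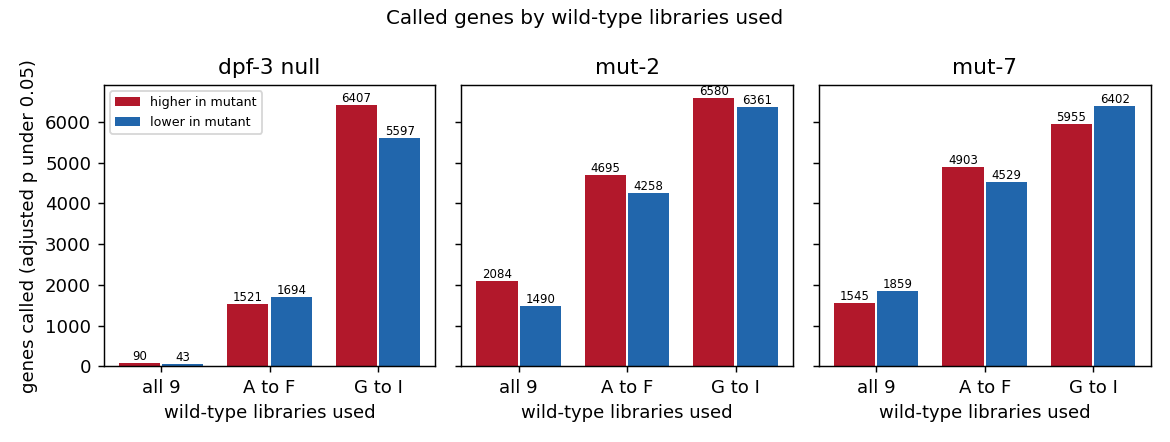
Number of genes called higher and lower (y axis, bars from 0) in each mutant against all 9 wild-type libraries, wild type A to F or wild type G to I (x axis). For the dpf-3 null 90 genes were higher against all 9 libraries, 1521 against A to F and 6407 against G to I.

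Of 30 lists, the set test with preset correlation called 21 in the dpf-3 null, 14 in mut-2 and 13 in mut-7. With an estimated correlation the calls that held were the small RNA targets in all 3 mutants, the intracellular pathogen response in mut-2 and mut-7, and the cuticle collagens in mut-7. With the preset correlation the first was not called in the dpf-3 null against G to I (adjusted p = 0.07), nor the second in mut-7 against A to F (0.24).

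The mutants were also compared in pairs. Between the dpf-3 null and mut-2, 942 genes were higher and 1168 lower in the dpf-3 null. cest-2.2 was higher in the dpf-3 null by 7.84 on the log2 scale (SE 0.58, adjusted p = 3.54e-07) and R13D11.4 by 5.98 (SE 0.28, adjusted p = 1.11e-09), while tbc-18 and Y73B3A.20 had no counts in mut-2 worms. ZK488.5 had no counts in the dpf-3 null and 17.9 CPM in mut-2 worms, and the neighbouring ZK488.6, K06H6.1 and C14C6.6 were lower in the dpf-3 null (-9.36, -8.97 and -8.69; adjusted p = 0.000926, 0.00503 and 0.00365). Between the dpf-3 null and mut-7, 1351 were higher and 1048 lower in the dpf-3 null. AC8.3, AC8.10, AC8.4 and F08F3.1 had no counts in mut-7 worms, and ZK488.6, K06H6.1 and K06H6.2 (WBGene00019450) were lower in the dpf-3 null (-9.61, -9.47 and -9.34; adjusted p = 0.000652, 0.00327 and 0.00632). Between mut-2 and mut-7, 881 genes were higher and 493 lower in mut-2 worms. cest-2.2, D1014.6 (WBGene00017019) and R13D11.4 were lower in mut-2 than in mut-7 worms (-8.41, -6.65 and -5.92; adjusted p = 1.25e-07, 0.000103 and 9.94e-10). With A to F 3787 and 4568, 3717 and 4936, and 3010 and 4636 were higher and lower. G to I gave 4062 and 4296, 4850 and 4537, and 3477 and 4185. Fits of the 2 mutants alone called 8687, 8988 and 7672, more than above. Controls enter these contrasts only through filter, scaling and spread.

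In all 3 mutants 23 genes were higher and 13 lower than wild type, where 1.09 and 0.448 would be shared if the calls were independent. F07B7.1 was at 9.83, 9.49 and 12.5 CPM in the dpf-3 null, mut-2 and mut-7, and ZC15.3 at 9.17, 8.38 and 11.9 CPM. F07B7.2 rose by 4.22, 3.75 and 4.34 on the log2 scale and C38D9.2 by 3.47, 3.18 and 4.19. F55B11.6 rose by 3.01, 3.19 and 4.16, col-164 by 3.33, 5.02 and 7.31 and col-114 by 3.86, 5.64 and 7.68. Against wild type A to F 656 were higher and 449 lower in all 3, and against G to I 4354 and 4655.

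By pairs of mutants, the dpf-3 null and mut-2 shared 41 higher and 23 lower genes, with 23 called in opposite directions, against 11.5 and 3.93 if independent. The dpf-3 null and mut-7 shared 31 and 19, with 45 opposite, against 8.53 and 4.90. mut-2 and mut-7 shared 910 and 831, with 150 opposite, against 197 and 170. Shared controls alone make fold changes correlate. Across genes, which are not independent replicates, Pearson's r was 0.767 for the dpf-3 null and mut-2, 0.35 for the dpf-3 null and mut-7 and 0.675 for mut-2 and mut-7. Simulated unchanged groups gave 0.249, 0.249 and 0.252, and 0 genes called in both. They carry no shift between A to F and G to I, so cannot separate it from genotype. Covariances were 1.573, 0.553 and 0.899 (simulated 0.121, 0.122 and 0.123). With wild type divided 2 ways between mutants, which may keep that shift, r was 0.685 and 0.792, 0.187 and 0.45, and 0.534 and 0.743. Spearman's rho was 0.48, 0.205 and 0.557 (simulated 0.224, 0.223 and 0.22), not exceeding unchanged groups for the dpf-3 null and mut-7. With A to F as controls rho was 0.297, 0.33 and 0.638 (simulated 0.306, 0.298 and 0.298), r was 0.6, 0.611 and 0.864 (simulated 0.335, 0.325 and 0.322) and the covariances 0.415, 0.617 and 1.873. Against A to F alone, the pairs shared 833, 812 and 3226 higher genes and 740, 717 and 2583 lower ones.

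X-linked and autosomal genes were compared by two-sided Fisher tests in which genes are not independent replicates. In the dpf-3 null 12 of 2334 X-linked genes fell, against 31 of 13964 autosomal genes (odds ratio 2.32, adjusted p = 0.029). The 12 include the null's set at the left end of X, and no test left it out. The ratio was 1.63 against A to F, 0.27 against G to I, 0.526 by DESeq2 and 3.57 in a fit of the 2 groups. Without dpf-3 null A, B or C it was 4.99, 3.74 and 3.74. In 10 of the other settings the unadjusted p was over 0.05. The odds ratio for higher genes was 1.2 (adjusted p = 0.54). In mut-2 worms the ratio was 1.21 for higher genes (adjusted p = 0.0038, lost in 11 settings) and 0.552 for lower ones (adjusted p = 2.9e-11), and in mut-7 worms 1.06 (adjusted p = 0.44) and 0.559 (adjusted p = 5.8e-13). For higher genes it was 0.7, 0.828 and 0.639 against A to F in the dpf-3 null, mut-2 and mut-7, and 3.47, 3.05 and 2.96 against G to I. For lower genes in mut-2 and mut-7 it was 0.846 and 1.22 against A to F, and 0.248 and 0.245 against G to I. Among 106 tested pseudogenes, 1 rose in the dpf-3 null (odds ratio against protein-coding genes 1.74, adjusted p = 0.57), 23 in mut-2 worms (1.9, adjusted p = 0.024) and 23 in mut-7 worms (2.67, adjusted p = 0.00054). In mut-2 and mut-7 that ratio was 3.08 and 2.9 against A to F (adjusted p = 5.2e-07 and 9.6e-07) but 0.674 and 0.655 against G to I (adjusted p = 0.1 each).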

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

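The tests of the patterns weighed here were chosen only after the results were seen. In 7 of 100 groups of wild-type values, 1 library lay far from the other 8, all 7 too near 0 to judge chance. ZK488.6 was at 0.598 CPM in wild type G and at 0 to 0.282 CPM in the others. col-102 was at 0.0332 CPM in wild type G and had no counts in the others. grl-25 was at 0.0997 CPM in wild type G and at most 0.0382 CPM elsewhere, cut-1 at 0.199 and 0.0312 CPM, col-2 at 0.432 and 0.114 CPM and col-37 at 0.864 and 0.0368 CPM. col-114 was at 0.114 CPM in wild type C and at most 0.0368 CPM elsewhere. Intervals with no gene name took 0.6401% of counts in mut-2 and 0.6378% in mut-7 worms, against 0.561% in wild type (n = 3, 3 and 9). The exact two-sided permutation test gave p = 0.00455 each (adjusted p = 0.0205).

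The first pattern weighed was the division of the wild-type libraries into A to F and G to I. A mixed-up label, with a mutant genotype in G to I, was ruled out as the cause: for the dpf-3 null by dpf-3 itself, at 260 CPM in G to I and 8.08 CPM in the null, and for mut-2 and mut-7 by the reported small RNA targets, of which 9 of 11 rose in each while their median log2 fold change was -0.33 in G to I against A to F. Library size was ruled out, since the ratio of mean total counts, G to I over A to F, was 1.03. Of the tested sperm, oocyte and vitellogenin genes, 100% were higher in G to I, which is consistent with worms further in development at collection; the labels state L4 for all, and the same values were seen before the test was chosen.

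The second pattern was the rise of the reported small RNA targets in mut-2 and mut-7 worms. The position of the mutants between the wild-type sets cannot be the whole cause. Of the genes, 9 were higher in mut-2 and mut-7 than in A to F and than in G to I. Genes that peak between those stages remain possible for single members, as bli-1, at 1.3 CPM in A to F and 39.6 CPM in G to I, reached 748 CPM in mut-2 and 643 CPM in mut-7 worms. Reads shared between exact copies cannot be the whole cause, since 8 called genes were left without them. Near copies and intervals were not tested. A loss of small RNA silencing, the explanation the genotypes give, was not tested, as small RNAs were not measured.

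The third pattern was the genes with no counts in a mutant. Of tested genes at any level, counting copies once, 113 were at 0 in the dpf-3 null, 39 in mut-2 and 19 in mut-7 worms. Counting noise at low expression cannot be the whole cause in mut-2 and mut-7, since a Poisson chance of 0 from the lowest wild-type library was under 0.05 after Bonferroni correction in 9 cases (2 and 7); in the dpf-3 null there were 0, and for the other genes it remains open. A deleted or diverged stretch of the strain's genome could account for some. Of genes with at least 1 CPM in both wild-type sets there were 7 cases in 6 genes, with Y73B3A.20 in both mutants, and 2 neighbouring pairs among them gave a permutation p of 1e-04, the smallest that 10000 draws can give, with a mean of 0.0018 pairs by chance and at most 1. This test was altered after its first run to keep 1 of each set of copies, with the same p before and after, and that of counting noise to take in genes of all levels. Silencing of the genes would look the same in RNA and was not tested.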

How the results depend on the processing

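The counts depended most on which wild-type libraries stood as control, and the cause of each shift here was not tested unless a clause gives it. Of the values of named genes under other settings 3571 kept their direction and their side of the threshold, 108 kept the direction and lost the call (67 higher, 41 lower) and 0 reversed. Of the set tests 2488 kept both, 203 lost and 96 gained a call, and 90 reversed. RLE and upper-quartile scaling, the stricter filter, removal of ribosomal and mitochondrial RNA and fits without robust estimation left all counts of called genes within 1.5 times; no filter gave 52 higher genes in the dpf-3 null. Counts are given for the dpf-3 null, mut-2 and mut-7, then for the pairs dpf-3 null and mut-2, dpf-3 null and mut-7, and mut-2 and mut-7, then for genes called the same way in those pairs and in all 3 mutants. The same letter does not pair samples: correlations of 18 pairs of the same letter ran from -0.138 to 0.0884, with 0 above 0.1. DESeq2 gave no adjusted p for 3073, 1537 and 1537 genes of the 3 mutants.

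With wild type A to F only, 1521, 4695 and 4903 genes were higher and 1694, 4258 and 4529 lower, the pairs gave 8355, 8653 and 7646, and 1573, 1529, 5809 and 1105 were called the same way; 11 lists were called in the dpf-3 null. With G to I only, 6407, 6580 and 5955 were higher and 5597, 6361 and 6402 lower, the pairs gave 8358, 9387 and 7662, and 10294, 9517, 10742 and 9009 went the same way. With A to C only, 1037, 4649 and 4858 were higher and 1267, 3990 and 4075 lower, the pairs gave 8754, 9010 and 8146, and 1094, 1030, 5461 and 734 went the same way, with 10 lists. With D to F only, 2321, 4563 and 5036 were higher and 1998, 4187 and 4565 lower, the pairs gave 8711, 9032 and 7913, and 1991, 2236, 5889 and 1464 went the same way, with 12 lists. With the replicate block and wild type A to C, 974, 4551 and 4768 were higher and 1159, 3890 and 3931 lower, the pairs gave 8523, 8808 and 7920, and 1013, 931, 5282 and 657 went the same way, with 9 lists.

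Fits of only the 2 groups compared gave 26 higher and 16 lower in the dpf-3 null, 1179 higher in mut-2, 8687, 8988 and 7672 for the pairs, and 24, 20, 1159 and 17 the same way. DESeq2 gave 310 higher and 1229 lower in the dpf-3 null and 2862 lower in mut-2, with 564, 188 and, in all 3, 153 the same way. A minimum of 2-fold left 30, 810 and 756 higher and 19, 420 and 376 lower, 913, 1062 and 633 for the pairs and 33, 30 and 549 the same way. An adjusted p under 0.01 left 31, 1319 and 991 higher and 14, 770 and 1049 lower, 1142, 1354 and 786 for the pairs and 26, 22, 933 and 20 the same way. An estimated correlation left 1, 2 and 3 lists and fry 4, 9 and 7. Calls against both wild-type sets, chosen after seeing the data, were 407 higher and 205 lower in the dpf-3 null and 2269 lower in mut-2. By those calls the dpf-3 null and mut-2 shared 153 higher genes, the dpf-3 null and mut-7 88 higher and 76 lower, and all 3 mutants 66 and 64.

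Leaving out 1 library at a time gave 26 to 103 higher and 11 to 45 lower genes in the dpf-3 null, 1204 to 2111 and 818 to 2097 in mut-2, and 974 to 1628 and 1363 to 2346 in mut-7. The pairs gave 1414 to 2458, 1811 to 2781 and 852 to 1656, the genes called the same way were 22 to 71, 19 to 50, 1245 to 2071 and 16 to 38, and the lists called 17 to 22, 14 to 16 and 10 to 13.

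The odds ratio of X for higher genes was under 1 in the dpf-3 null, mut-2 and mut-7 at 0.7, 0.828 and 0.639 with A to F, 0.751, 0.786 and 0.604 with A to C, 0.714, 0.895 and 0.632 with D to F and 0.785, 0.809 and 0.601 with the block. It was also under 1 in the dpf-3 null in a fit of the 2 groups (0.494) and without dpf-3 null A (0.641) or C (0.779), and in mut-7 without mut-7 B (0.918). For lower genes in mut-7 it was over 1 at 1.22, 1.3, 1.18 and 1.3 in the same order, and the ratios for the dpf-3 null are given above.

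Set tests that reversed are given by adjusted p, pointing up unless marked. With A to F in the dpf-3 null they were major sperm proteins (5.6e-25), other sperm genes (1e-07), nspd (2.3e-05), oocyte (0.0013), meiosis (0.65), Argonautes (0.029), mutator foci (0.81), P granule (0.17), vitellogenins (0.025) and DNA damage (0.91), and down histones (0.56), moulting (0.029), neurons (0.2) and neuropeptides (0.25). In mut-2 they were major sperm proteins (2.4e-25), other sperm genes (1.2e-14), nspd (3.9e-07) and vitellogenins (0.00012), and in mut-7 oocyte (0.00016) and, down, chemoreceptors (0.05). With G to I they were innate immune in the dpf-3 null (0.57), histones in mut-2 (1.8e-06) and, in mut-7, histones (2.9e-08), neurons (0.0078) and neuropeptides (0.02), and down major sperm proteins (1.6e-51), other sperm genes (4.6e-15), nspd (1.3e-17), Argonautes (0.024) and vitellogenins (0.011).

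With A to C in the dpf-3 null they were major sperm proteins (7.7e-24), other sperm genes (3.3e-06), nspd (7.6e-05), oocyte (0.036), meiosis (0.75), mutator foci (0.37), P granule (0.19), vitellogenins (0.078) and DNA damage (0.84), and down histones (0.0017), moulting (0.0027), pharynx (0.77), neurons (0.12), neuropeptides (0.079), unfolded protein responses (0.75) and ribosomal proteins (0.37). In mut-2 they were major sperm proteins (3.1e-21), other sperm genes (4.9e-12), nspd (5.7e-06) and vitellogenins (0.0019), and in mut-7 oocyte (0.00042). With the block in the dpf-3 null they were, in the same order, 1.3e-23, 5.3e-06, 0.00011, 0.051, 0.74, 0.39, 0.22, 0.071 and 0.86, and down 0.0015, 0.00032, 0.78, 0.16, 0.097, 0.78 and 0.39. In mut-2 they were 2.4e-22, 8.7e-12, 7.5e-06 and 0.00012, and in mut-7 0.00079.

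With D to F in the dpf-3 null they were major sperm proteins (2.7e-14), other sperm genes (8.5e-06), nspd (0.0012), oocyte (0.00019), meiosis (0.55), Argonautes (0.018), P granule (0.15) and vitellogenins (0.054), and down moulting (0.045), neurons (0.3) and neuropeptides (0.79). In mut-2 they were major sperm proteins (9.8e-21), other sperm genes (1.4e-13), nspd (3.6e-06) and vitellogenins (0.00085), and in mut-7 oocyte (3.4e-05) and, down, xenobiotic response (0.026) and chemoreceptors (0.04).

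With their direction kept, 20, 15, 16, 22 and 16 set calls were lost with A to F, G to I, A to C, D to F and the block. Those with A to C and the block were all lost with A to F too, and so were those with D to F apart from mutator foci (adjusted p = 0.88), histones (0.087) and DNA damage (0.98) in the dpf-3 null and F-box in mut-2 (0.05). By adjusted p, those with A to F were muscle (0.086), pharynx (0.9), heat shock (0.074), unfolded protein responses (0.61) and ribosomal proteins (0.81) in the dpf-3 null, oocyte (0.25), mutator foci (0.27), intestine (0.23), neuropeptides (0.61), DNA damage (0.19) and xenobiotic response (0.67) in mut-2, and meiosis (0.19), mutator foci (0.51), P granule (0.88), muscle (0.94), DNA damage (0.51), intracellular pathogen response (0.24), innate immune (0.81), F-box (0.51) and oxidative phosphorylation (0.074) in mut-7. Those with G to I were mutator foci (0.089), small RNA targets (0.07), peptidases (0.53), collagens (0.58), muscle (0.067), pharynx (0.077), heat shock (0.46) and ribosomal proteins (0.12) in the dpf-3 null, F-box (0.24) and ribosomal proteins (0.79) in mut-2, and muscle (0.072), innate immune (0.06), F-box (0.43), ribosomal proteins (0.33) and oxidative phosphorylation (0.93) in mut-7.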

Other observations

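Tests in this part were chosen only after the results were seen. A stretch of chromosome V from nhr-155 (V:539460-541485), a nuclear hormone receptor gene, to ZK488.5 (V:593259-595677) held 10 of the genes that rose over 16-fold in mut-2 worms. K06H6.2 was at 89.9 CPM in mut-2 and 149 CPM in mut-7 worms, against 0.0933 CPM in wild type A to F and 4.71 CPM in G to I. As a hypothesis, neighbouring genes may have risen together: 17 neighbouring pairs among 80 genes gave a permutation p of 1e-04, the smallest that 10000 draws can give, with a mean of 0.387 and at most 4 pairs by chance.

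In the list tests here, estimated marks the adjusted p with an estimated correlation, and unadjusted and DESeq2 counts are higher, then lower. Of 51 other sperm genes edgeR called 0 in the dpf-3 null (unadjusted 0 and 22, DESeq2 0 and 29), 1 rose in mut-2 and 2 rose in mut-7, and adjusted over the list alone 0 were called in mut-2 and 1 rose in mut-7. Other sperm genes as a set were called lower in the dpf-3 null (adjusted p = 1.2e-06; 0.89 estimated) and higher in mut-7 (adjusted p = 0.024; 0.9 estimated), not in mut-2 (0.27); both turned, with the dpf-3 null higher against A to F (1e-07) and mut-7 lower against G to I (4.6e-15). Of 9 nspd genes, abundant in sperm, edgeR called 0 in any mutant, also when adjusted over the list alone; unadjusted, 7, 0 and 0 were lower in the dpf-3 null, mut-2 and mut-7, and by DESeq2 9, 7 and 0. These peptide genes as a set were called lower in the dpf-3 null (adjusted p = 0.026; 0.89 estimated), and higher there against A to F (2.3e-05), not in mut-2 (0.46) and mut-7 (0.6). Of 27 genes of mutator foci and RNA-dependent RNA polymerases edgeR called 0 in the dpf-3 null (unadjusted 2 and 0, DESeq2 0 and 0), 1 rose (rrf-2, an RNA-dependent RNA polymerase, from 19.5 CPM in A to F and 13.8 CPM in G to I to 59.6 CPM) and 6 fell in mut-2 and 1 rose and 3 fell in mut-7, and adjusted over the list alone 2 rose and 12 fell in mut-2 and 1 rose and 8 fell in mut-7. Genes of mutator foci as a set were called lower in the dpf-3 null, mut-2 and mut-7 (adjusted p = 0.0063, 0.013 and 0.024; 0.89 each estimated). Of 30 P granule and piRNA genes edgeR called 0 in the dpf-3 null (unadjusted 0 and 4, DESeq2 0 and 3), 12 fell in mut-2 and edgeR called 0 in mut-7 (unadjusted 1 and 9, DESeq2 0 and 3), and adjusted over the list alone 20 fell in mut-2. P granule and piRNA genes as a set were called lower in the dpf-3 null, mut-2 and mut-7 (adjusted p = 0.00029, 7.1e-07 and 0.024; 0.89, 0.89 and 0.9 estimated). Of 72 histone genes edgeR called 0 in the dpf-3 null (unadjusted 0 and 7, DESeq2 0 and 7), 2 rose and 14 fell in mut-2 and 1 rose and 12 fell in mut-7, also when adjusted over the list alone. Histone genes as a set were called lower in mut-2 (adjusted p = 0.012; 0.89 estimated) and higher in the dpf-3 null (adjusted p = 0.038; 0.89 estimated), not in mut-7 (0.24); both turned, with mut-2 higher against G to I (1.8e-06) and the dpf-3 null lower against A to C (0.0017).

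Of 8 dipeptidyl peptidase genes 1 fell in the dpf-3 null (dpf-3), edgeR called 0 in mut-2 (unadjusted 0 and 0, DESeq2 0 and 0) and 1 fell in mut-7 (dpf-4, at 92.7 CPM against 105.6 CPM in A to F), also when adjusted over the list alone. The peptidase set, which holds dpf-3 and was not tested without it, was called lower in the dpf-3 null (adjusted p = 0.026; 0.25 estimated, 0.53 against G to I), not in mut-2 (0.74) and mut-7 (0.48). Of 25 moulting genes edgeR called 0 in the dpf-3 null (unadjusted 0 and 3, DESeq2 0 and 3), 2 rose and 2 fell in mut-2 and 2 rose and 3 fell in mut-7, also when adjusted over the list alone. Moulting genes were not called as a set (adjusted p = 0.51, 0.46 and 0.46). Of 4 male genes edgeR called 0 in any mutant, also when adjusted over the list alone; unadjusted, 0, 1 and 0 were higher, and by DESeq2 0, 1 and 2. Male genes were not called as a set (adjusted p = 0.8, 0.74 and 0.78). Of 27 muscle genes 1 rose in the dpf-3 null, 1 rose and 1 fell in mut-2 and 5 rose in mut-7, and adjusted over the list alone 2 rose in the dpf-3 null. Muscle genes as a set were called higher in the dpf-3 null and mut-7 (adjusted p = 3.4e-06 and 0.0038; 0.51 and 0.89 estimated, 0.086 and 0.94 against A to F, 0.067 and 0.072 against G to I), not in mut-2 (0.74). Of 15 pharynx genes edgeR called 0 in the dpf-3 null (unadjusted 2 and 0, DESeq2 1 and 0), 2 rose in mut-2 and 1 fell in mut-7, and adjusted over the list alone 1 rose in the dpf-3 null. Pharynx genes as a set were called higher in the dpf-3 null (adjusted p = 0.0091; 0.89 estimated), not in mut-2 (0.63) and mut-7 (0.46). Of 25 intestine genes edgeR called 0 in the dpf-3 null (unadjusted 1 and 4, DESeq2 0 and 3), 8 rose in mut-2 and 3 rose and 1 fell in mut-7, and adjusted over the list alone 1 fell in the dpf-3 null. Intestine genes as a set were called higher in mut-2 (adjusted p = 0.024; 0.81 estimated), not in the dpf-3 null (0.34) and mut-7 (0.48).

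Of 26 neuron genes edgeR called 0 in the dpf-3 null (unadjusted 0 and 0, DESeq2 0 and 0), 2 rose in mut-2 and edgeR called 0 in mut-7 (unadjusted 0 and 1, DESeq2 0 and 0), also when adjusted over the list alone. Neuron genes as a set were called higher in the dpf-3 null (adjusted p = 0.0058; 0.89 estimated), not in mut-2 (0.34) and mut-7 (0.51). Of 125 neuropeptide genes 1 fell in the dpf-3 null, 16 rose and 3 fell in mut-2 and 6 rose and 4 fell in mut-7, and adjusted over the list alone 14 rose and 2 fell in mut-2 and 5 rose and 4 fell in mut-7. Neuropeptide genes as a set were called higher in the dpf-3 null and mut-2 (adjusted p = 0.0038 and 0.00098; 0.89 each estimated), not in mut-7 (0.52). Of 21 heat shock genes 1 rose in the dpf-3 null, 1 rose and 3 fell in mut-2 and 1 rose and 8 fell in mut-7, also when adjusted over the list alone. Heat shock genes as a set were called higher in the dpf-3 null (adjusted p = 0.024; 0.81 estimated), not in mut-2 (0.054) and mut-7 (0.13). Of 22 unfolded protein response genes of the endoplasmic reticulum and mitochondria edgeR called 0 in the dpf-3 null (unadjusted 6 and 1, DESeq2 0 and 0), 10 rose and 2 fell in mut-2 and 1 rose and 4 fell in mut-7, and adjusted over the list alone 12 rose and 3 fell in mut-2. These stress genes as a set were called higher in the dpf-3 null and mut-2 (adjusted p = 0.0023 and 0.0031; 0.81 each estimated), not in mut-7 (0.76). Of 29 DNA damage genes edgeR called 0 in the dpf-3 null (unadjusted 0 and 2, DESeq2 0 and 1), 2 rose and 9 fell in mut-2 and 2 rose and 8 fell in mut-7, and adjusted over the list alone 2 rose and 10 fell in mut-2. DNA damage genes as a set were called lower in the dpf-3 null, mut-2 and mut-7 (adjusted p = 0.00025, 0.003 and 0.013; 0.89 each estimated). Against A to F the dpf-3 null turned for mutator foci (0.81), P granule (0.17) and DNA damage genes (0.91), up, and neuron (0.2) and neuropeptide genes (0.25), down.

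Of 240 innate immune effectors 2 fell in the dpf-3 null, 51 rose and 36 fell in mut-2 and 58 rose and 24 fell in mut-7, and adjusted over the list alone 2 rose and 3 fell in the dpf-3 null, 54 rose and 40 fell in mut-2 and 64 rose and 29 fell in mut-7. Immune effector genes as a set were called lower in the dpf-3 null (adjusted p = 0.021; 0.81 estimated) and higher in mut-7 (adjusted p = 0.012; 0.81 estimated), not in mut-2 (0.34). Of 203 xenobiotic response genes 2 rose in the dpf-3 null, 55 rose and 12 fell in mut-2 and 41 rose and 28 fell in mut-7, and adjusted over the list alone 9 rose and 3 fell in the dpf-3 null, 59 rose and 15 fell in mut-2 and 44 rose and 33 fell in mut-7. Xenobiotic response genes as a set were called higher in mut-2 (adjusted p = 0.00057; 0.89 estimated), not in the dpf-3 null (0.052) and mut-7 (0.47). Of 251 F-box and BATH genes 1 fell in the dpf-3 null, 77 rose and 19 fell in mut-2 and 41 rose and 17 fell in mut-7, and adjusted over the list alone 81 rose and 26 fell in mut-2 and 42 rose and 19 fell in mut-7. F-box and BATH genes as a set were called higher in mut-2 and mut-7 (adjusted p = 0.00025 and 0.013; 0.44 and 0.81 estimated), not in the dpf-3 null (0.65). Of 190 chemoreceptor genes 1 rose in the dpf-3 null, 23 rose and 7 fell in mut-2 and 23 rose and 13 fell in mut-7, and adjusted over the list alone 23 rose and 4 fell in mut-2. Chemoreceptor genes were not called as a set (adjusted p = 0.63, 0.23 and 0.74). Of 32 oxidative phosphorylation genes edgeR called 0 in the dpf-3 null (unadjusted 1 and 0, DESeq2 0 and 0), 1 fell in mut-2 and 5 fell in mut-7, and adjusted over the list alone 0 were called in mut-2 and 4 fell in mut-7. Oxidative phosphorylation genes as a set were called lower in mut-7 (adjusted p = 0.03; 0.89 estimated), not in the dpf-3 null (0.23) and mut-2 (0.91). Here only the set calls of P granule and unfolded protein response genes in mut-2 held against A to F (0.00088 and 0.012) and against G to I (7.4e-09 and 0.0022). Median, mean and test differed in sign for the other sperm genes in mut-7, the nspd genes in mut-7, the dipeptidyl peptidase genes in mut-2, the moulting genes in the dpf-3 null and mut-7, the male genes in the dpf-3 null, the intestine genes in the dpf-3 null, mut-2 and mut-7, the unfolded protein response genes in mut-7, the innate immune effectors in mut-2 and the chemoreceptor genes in the dpf-3 null and mut-7.

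Intervals with no gene name were tested in a fit of their own. Of 4226 tested, 68 were higher and 21 lower in the dpf-3 null, 463 and 142 in mut-2 and 314 and 143 in mut-7 worms. Among intervals higher than each of the wild-type sets, 55 were so in all 3 mutants. Pairs of mutants shared 60 (dpf-3 null and mut-2), 62 (dpf-3 null and mut-7) and 191 (mut-2 and mut-7) of these; the mutants share their controls and equal copies count separately, so chance sharing was not judged. Against wild type A to F 91, 480 and 443 were higher and 92, 262 and 398 lower, and against G to I 1108, 1496 and 904 higher and 265, 348 and 298 lower. The interval V:8829126-8829723, beside F07B7.2, with counts equal to those of V:8871220-8871817, so that the copies cannot be told apart, was at 1.84 CPM in A to F, 1.55 CPM in G to I and 39, 29.3 and 41.4 CPM in the dpf-3 null, mut-2 and mut-7.

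All 5 exact lengths of at least 1000 bases that at least 5 tested intervals shared were examined; intervals are not independent, so the grouping is a hypothesis only. Of 12 tested intervals of 1611 bases, 12 were higher in mut-2 worms, against 95 of 325 others (Fisher exact test, adjusted p = 1e-05), 5 in mut-7 and 2 in the dpf-3 null. Of 10 tested intervals of 2337 bases, 6 were higher in the dpf-3 null, against 38 of 327 others (adjusted p = 0.0038), and 8 each in mut-2 and mut-7 worms (adjusted p = 0.0079). The other lengths did not differ from the rest (adjusted p = 0.11 or more): of 5 each, 0, 3 and 1 of 1242 bases, 0, 1 and 0 of 1286 bases and 0, 0 and 4 of 2075 bases were higher in the dpf-3 null, mut-2 and mut-7.

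Other splits of the same libraries tested whether a random division could give as many called genes. For the dpf-3 null against all 9 wild-type libraries, 2 of 100 splits gave as many as the real 133, and the highest other gave 12723; for mut-2 it was 2 of 100 with 3574 and 12180, and for mut-7 2 of 100 with 3404 and 11602. The other split in each case set wild type G, H and I against the rest, so random division is excluded only beside that structure. Against wild type A to F, 1 of 84 splits, the real one, gave 3215, 8953 and 9432 genes. The highest other gave 1513, 426 and 420, and for the dpf-3 null and mut-7 set wild type D, E and F apart. So random division is excluded, but not a difference between sets of samples. The 10 splits of each pair of mutants are too few for a share under 0.05; the real ones gave 2110, 2399 and 1374 genes and the highest other 0.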
